A study of Caenorhabditis elegans with 16 samples.

How the data were processed

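RNA from staged embryos of the nematode Caenorhabditis elegans was measured on one-colour Agilent arrays of a custom 44k design. Each of the 16 samples was made from 50 embryos. Per the labels' protocols, total RNA was amplified by 2 rounds of in vitro transcription, labelled with Cy3, and an equal mass of labelled RNA was put on every array. The values therefore compare the makeup of the RNA between samples, and not the amount of RNA per embryo. The labels describe the samples as biological replicates.

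The deposited scanner files hold spot intensities, in arbitrary brightness units, made with Agilent Feature Extraction version 9.5.3.1 per the file headers. The processed signal in them is an intensity after background subtraction, spatial detrending and a lower limit for dim spots, with no scaling between arrays. The files also hold the median signal, the local background and the flags for saturated, outlying and well-above-background spots. A deposited value table of the whole series was set against the scanner files. For the 33814 probes it lists, it gives the processed intensity of the same array, rounded (largest relative difference 5e-05), unscaled and not logged. It leaves out 9898 of the 20074 B probes and all 91 C. briggsae probes, and keeps every A and C probe. The medians of its 16 columns differ between arrays, so no centring was applied to it.

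The array has 45220 spots, of which 1417 are controls. The 43712 C. elegans probes stand for 20074 genes, with an A probe that the designers ranked best and further B and C probes. A probe was kept if it was well above background on at least 2 of the 16 arrays. This left 32737 probes and 17779 genes, of which 5698 had 1 kept probe, 9204 had 2 and 2877 had 3. The log2 of the processed signal was shifted by each array's 75th percentile over all non-control probes. Spots with an outlier flag were left out, saturated spots were not, and a gene's value was the mean over its kept probes. One gene had no value at the 190-cell stage, so comparisons with that stage tested 17778 genes. A gene was called detected on an array when any of its kept probes was well above background there.

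Groups were taken from the labels. There were 3 arrays each of N2 embryos at the 4-cell, 28-cell and 95-cell stages, 2 each at the 55-cell and 190-cell stages, and 3 of Hawaiian embryos at the 4-cell stage. The strain label is blank for 28-cell replicate C, which was grouped by its title. The arrays lay on 5 slides and were scanned on 1 day. Replicates of a group correlated at r between 0.977 and 0.990 across genes, and no replicate pair shared a value on any probe.

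All 16 arrays entered one linear model with a mean per group, in limma 3.58.1 (R 4.3.3) with moderated tests. P-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. The time course was tested with a moderated F test over the 5 N2 stages. On simulated arrays with the real genes' spread and 100 genes changed 2-fold and 100 changed 4-fold among 17717, the fit recovered 35% of 2-fold and 80% of 4-fold changes for the 28-cell against the 4-cell stage. It recovered 29% and 71% for the 190-cell against the 4-cell stage, and 30% and 83% for the strain comparison, with 7 false calls in each. The adjusted threshold loosens as more genes change. The real comparisons called a far larger share of genes than was changed here, so the simulated recovery need not hold for them. The number of arrays limits the precision.

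The groups, the gene summary, the filter, the scaling and the tests were chosen before the data were examined. Alternatives chosen at the same time were normexp background correction with an offset of 50, quantile and median scaling, no filter and a stricter filter, the A probe alone, the brightest probe, the deposited value table scaled to the 75th percentile of its own probes, the replicate letter or the slide as a block, only the arrays of the groups compared, and leaving out each array. The normexp correction was planned on the mean signal and was run on the median signal with the median background. A block for the scan day was not run, because all arrays share 1 day. After the data were seen, 3 more scalings were added: the 75th percentile of probes detected on all 16 arrays, the mean of 5 spike-in controls, and no scaling. The counts of genes called in the same direction under all 6 scalings, and the counts of genes that gained or lost detection, were also chosen after the data were seen.

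Probes carry WormBase gene IDs and no symbols, and 0 of the 17779 tested IDs matched an entry of the reference gene table, which names the assembly WBcel235. The files do not pair the IDs with gene names, so the gene lists fixed in advance could not be tested and pathways are not analysed here. The rule for named genes, fixed in advance, took called genes with a symbol, detected on at least 1 array of both groups and with every replicate of one group beyond every replicate of the other, in order of fold change. Without symbols the rule was applied to the IDs. To keep unnamed IDs few, only the top gene in each direction is given, for the 190-cell against the 4-cell stage and for the strains, which is fewer than the rule allowed. For a gene detected on no array of a group, the fold is a lower bound. It sets the mean of the bright group against, per array of the dim group, the higher of the probe's own value and the lowest signal among probes well above background. Two-sided exact permutation tests were used for values per array.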

Results

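The arrays followed N2, the standard laboratory strain of Caenorhabditis elegans, from the 4-cell embryo to stages of 28, 55, 95 and 190 cells, the first of which lies 80 minutes later and the last 200. The Hawaiian strain, a wild isolate, was measured at the 4-cell stage. In this animal the first divisions run on RNA supplied by the mother, and transcription from the embryo's own genome takes over during the stages sampled. The time course asks which transcripts appear, persist or disappear, and the strain comparison asks how far the 4-cell RNA differs between isolates.

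Embryos at the 4-cell stage held signal for fewer genes than later embryos. Genes detected per array numbered 14058 ± 840 (SD, n = 3) at the N2 4-cell stage, 15715 ± 240 (n = 3) at 28 cells, 15682 ± 490 (n = 2) at 55 cells, 15540 ± 726 (n = 3) at 95 cells and 15920 ± 504 (n = 2) at 190 cells. Hawaiian 4-cell arrays detected 14798 ± 610 genes (n = 3). The difference of the N2 4-cell arrays from the 10 later N2 arrays was -1639 genes (exact permutation test, two-sided, p = 0.0035, the smallest that 286 arrangements allow). The strains differed by 740.3 genes, and the exact permutation test gave p = 0.3, where 3 arrays against 3 cannot go below 0.1. The 75th percentile of the signal was also lower at the N2 4-cell stage, at 6786 ± 849, against 11817 ± 2186 at 28 cells and 15686 ± 1483 at 190 cells. The spike-in controls went the other way, with a log2 signal 0.57 higher on the N2 4-cell arrays than on the later N2 arrays (exact permutation test, two-sided, p = 0.035).

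**Figure D1:**
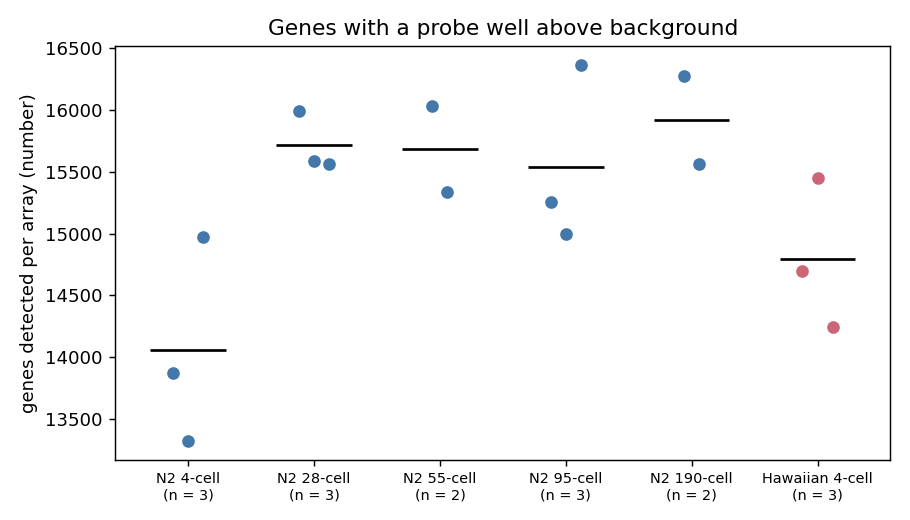
Number of genes with a probe well above background on each array (points) and the group mean (line), for the 5 N2 stages and Hawaiian 4-cell embryos. The 3 N2 4-cell arrays lie between 13324 and 14974 genes, all below the 10 later N2 arrays.

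Of the genes kept, 12119 were detected on every N2 array at all 5 stages. A further 1700 were detected on no N2 4-cell array and on every array of at least 1 later stage. Of these, 1001 were detected on every 28-cell array, 304 were first detected throughout a group at 55 cells, 156 at 95 cells and 239 at 190 cells. A group of 559 was detected at all 4 later stages, while 280 were detected throughout a group at 28, 55 or 95 cells and on neither array at 190 cells. Of the 1001 early genes, 663 were still detected on both 190-cell arrays and 214 on neither. Of the 12774 genes detected on every 4-cell array, 145 were detected on neither 190-cell array, and 19 were detected on no array of the 4 later stages. These counts record a signal crossing the background threshold, and gene probes gave less signal on the 4-cell arrays than on the later ones. A rule on every array or on none is met more easily by groups of 2 arrays than of 3. Genes detected on only some arrays numbered 1095 at 55 and 1243 at 190 cells, against 1777 at 28 and 1993 at 95.

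**Figure D2:**
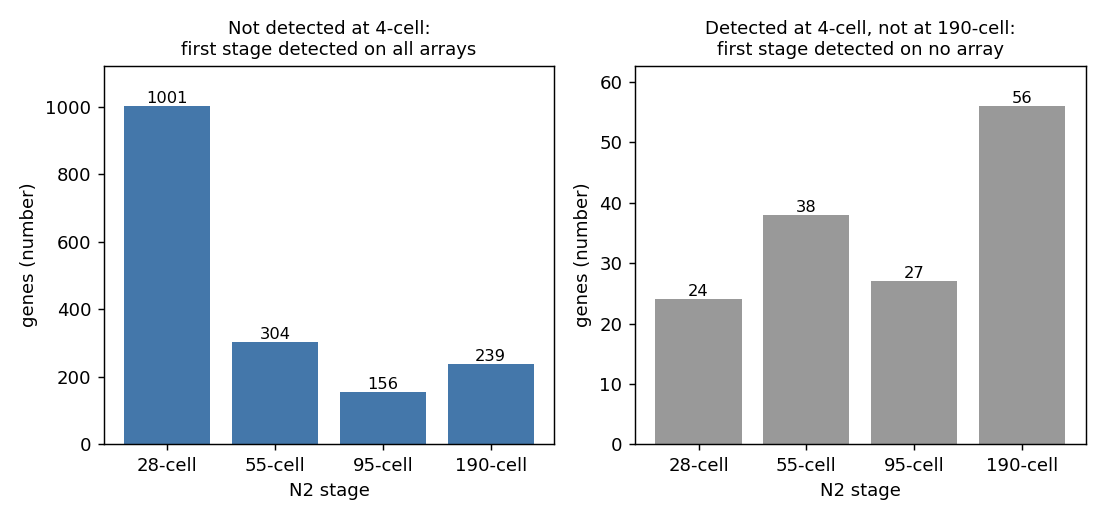
Left, genes detected on no N2 4-cell array, by the first stage at which every array detected them. Right, genes detected on every 4-cell array and on neither 190-cell array, by the first stage at which no array detected them. The largest class, 1001 genes, is first detected at the 28-cell stage. The 55- and 190-cell groups have 2 arrays, the other groups 3.

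Between the 4-cell and 28-cell stages, 1001 genes gained detection and 59 lost it. The lower bound of the fold reached 4-fold in 347 of the gains and 36 of the losses, and 45 of the losses were called lower under all 6 scalings. These bounds hold for the main scaling: always-detected probes as the scale move the median gene up by 1.20 log2 units at 28 cells, which widens the rises and narrows the falls. In limma's moderated test 11915 of 17779 genes were called, 4253 higher and 7662 lower at 28 cells. Of all genes, 3829 were higher and 1991 lower under each of the 6 scalings, and 3279 and 1727 of them by at least 2-fold. Spike-ins alone called 2022 lower and median scaling 3900 higher, so the most extreme scaling in each direction largely sets these counts. Of the 1001 gains, 909 were called higher, and 890 under all 6 scalings. In every comparison, detection and calls rest on the same signals of the same arrays, so the calls are no separate support. With the A probe alone 1601 genes gained detection and 96 lost it, and without 4-cell replicate B or 28-cell replicate A the losses were 110 and 97. The direction of the other calls depended on the scaling: 35.7% of calls were higher with the 75th percentile of all probes, 40.7% with quantile scaling, 30.8% with the median, 75.4% with the 75th percentile of always-detected probes, 75.5% with spike-ins and 63.9% with no scaling. The deposited value table, scaled to its own 75th percentile, gave 6112 higher and 4134 lower genes, and the A probe alone at the main scaling 4455 and 7004.

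The 3 later stages differed from the 4-cell stage as widely. Called genes numbered 12329 at 55 cells (3903 higher, 8426 lower), 12821 at 95 cells (4066 higher, 8755 lower) and 12675 at 190 cells (4155 higher, 8520 lower). Under all 6 scalings, 3834 genes were higher and 1169 lower at 55 cells, 4005 and 1288 at 95 cells, and 4060 and 1547 at 190 cells. Spike-ins alone called 1170, 1288 and 1551 genes lower at the 3 stages. The balance of higher and lower genes in these counts therefore depends on the scalings chosen. Detection was gained by 1119, 970 and 1240 genes at 55, 95 and 190 cells, and lost by 127, 114 and 145. The 55- and 190-cell groups have 2 arrays and the 95-cell group 3, and fewer arrays make both rules easier to meet. At 190 cells, under the main scaling, the bound reached 4-fold in 450 of the gains and 134 of the losses, and 127 of the losses were called lower under all 6 scalings. Spike-ins as the scale move the median gene up by 1.61 log2 units there, which narrows the falls. With always-detected probes as the scale, higher calls made up 70.7%, 70.8% and 72.8% at the 3 stages, against 31.7%, 31.7% and 32.8% with all probes. Quantile scaling gave 5073 higher of 11808 calls at 55 cells, 44.0% at 95 and 44.4% at 190, spike-ins 87.4%, 87.9% and 82.5%, and no scaling 70.9%, 65.1% and 70.9%. The deposited value table gave 5455 higher and 4680 lower genes at 55 cells, 5746 and 4698 at 95, and 5808 and 4776 at 190. With normexp correction 9549 genes were called at 190 cells, 4093 higher and 5456 lower. Without 55-cell replicate A, 771 genes were lower at 55 cells under all 6 scalings. With the A probe alone the gains were 1770, 1633 and 2074, and the losses at 95 and 190 cells 193 and 249. Losses at 55 cells were 268, 201 and 194 without 55-cell replicate A, 4-cell replicate A or 4-cell replicate B, losses at 95 cells were 239 and 176 without 95-cell replicate C or 4-cell replicate B, and losses at 190 cells were 293 without 190-cell replicate A.

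Many of the genes that differed at 28 cells also differed at 190 cells. Of the 3829 genes higher at 28 cells under all scalings, 2352 (61.4%) were also higher at 190 cells under all scalings and 103 were lower. Of the 1991 lower genes, 1010 (50.7%) were lower again and 64 were higher. The comparisons use the same 4-cell arrays. Independent lists of these sizes would share 874 higher and 173 lower genes. On 1 simulated set of arrays with the real genes' spread and no gene changed, fitted once, the comparisons shared 0 higher and 0 lower calls. Few genes are called at all where none changed, so that count shows nothing about the shared arrays. How much the shared arrays add to the overlap among genes that did change was not measured.

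WBGene00000217 ranked first among the genes detected in both groups and higher at 190 than at 4 cells. Its log2 level relative to the array's 75th percentile was -5.66 ± 1.14 (SD, n = 3) at 4 cells, 3.39 ± 0.19 (n = 3) at 28 cells, 4.37 ± 0.06 (n = 2) at 55, 4.70 ± 0.05 (n = 3) at 95 and 4.59 ± 0.17 (n = 2) at 190 cells. The log2 change was 10.25 ± 0.49 (SE, limma adjusted p = 9.18e-10), with 1 of its 2 probes detected, on 2 of the 3 4-cell arrays, and the other on none, so that it is no exact fold. The gene ranked next lay close, and was ahead with quantile scaling (11.22 against 11.08), no filter (6.50 against 6.38), slide as a block (10.36 against 10.22) and without 4-cell replicate A (10.03 against 9.59). WBGene00007290 ranked first among the genes detected in both groups and lower at 190 cells, from 4.94 ± 0.03 (n = 3) at 4 cells to -1.0 ± 0.18 (n = 3) at 28 cells, -3.45 ± 1.37 (n = 2) at 55, -5.32 ± 0.41 (n = 3) at 95 and -6.39 ± 0.14 (n = 2) at 190 cells. Its log2 change was -11.32 ± 0.41 (SE, adjusted p = 6.67e-11). That mean is no exact fold, since 2 of its 3 probes were not well above background at 190 cells, and the probe detected there gave -8.42. Over all 16 arrays 1 spot of the gene was saturated. The gene ranked next was ahead with the brightest probe (-9.99 against -8.42) and without 190-cell replicate A (-11.49 against -11.42). Over the 6 scalings the changes ranged from 10.25 to 11.85 and from -11.32 to -9.72.

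**Figure D3:**
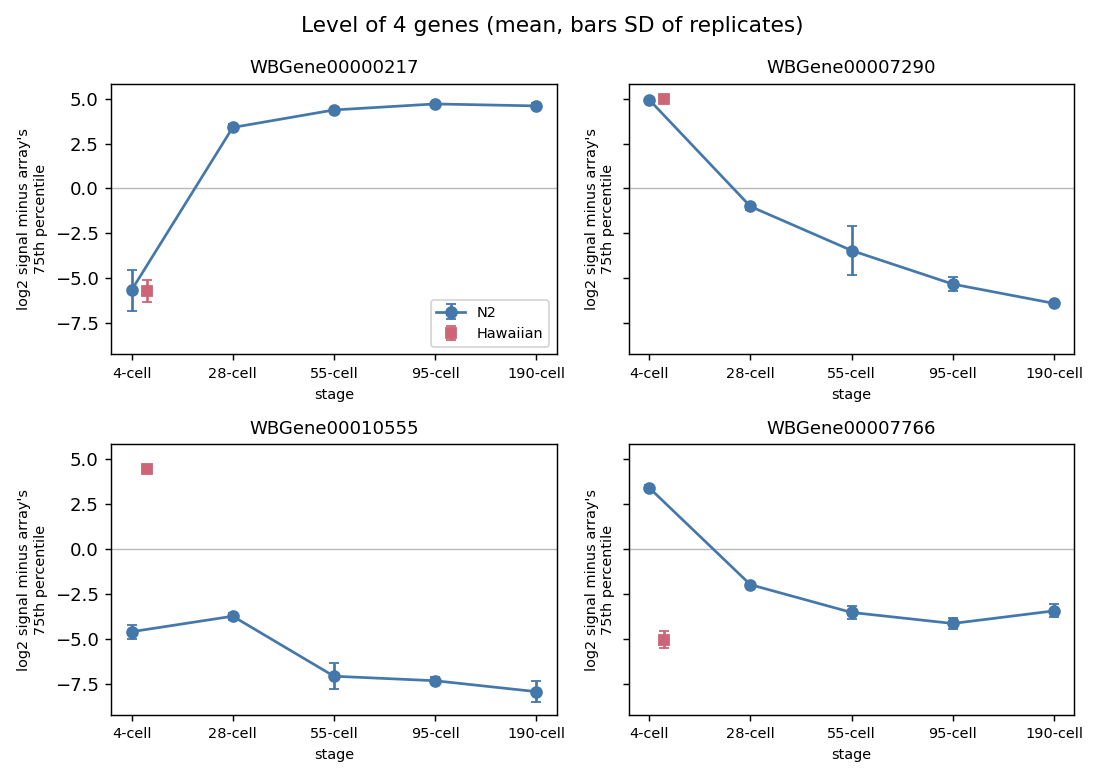
Level of the 4 genes named in the text (log2 signal minus the array's 75th percentile) in N2 embryos by stage and in Hawaiian 4-cell embryos. Points are group means and bars the SD of 2 or 3 arrays. WBGene00000217 rises from -5.66 to 3.39 by 28 cells, and WBGene00010555 lies at 4.44 in Hawaiian and -4.59 in N2 embryos.

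Steps between neighbouring later stages were smaller, but each also covered less time than the step from 4 to 28 cells. The counts and correlations were not adjusted for the time between stages, so they do not compare rates of change. Arrays of neighbouring later stages correlated at r between 0.943 and 0.957 across genes, against 0.795 to 0.824 for 28 cells with 4 cells and 0.747 to 0.771 for 190 cells with 4 cells. From 28 to 55 cells 4582 genes were called, 1990 higher and 2592 lower, and 1637 and 638 under all scalings. From 55 to 95 cells 3112 were called, 1502 higher and 1610 lower, and 811 and 711 under all scalings. From 95 to 190 cells 3780 were called, 1759 higher and 2021 lower, and 856 and 874 under all scalings.

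These 3 counts rested more on single arrays and on the scaling. Without 55-cell replicate A they were 2811 for 28 to 55 cells and 1929 for 55 to 95 cells, without 55-cell replicate B they were 2950 and 1972, and without 190-cell replicate A the last step called 2387. Under all scalings, the genes higher and lower from 28 to 55 cells were 854 and 301 without 55-cell replicate A and 596 and 397 without replicate B, and 1008 were higher without 28-cell replicate B. From 55 to 95 cells they were 389 and 462 without 55-cell replicate A, and 317 were lower without replicate B. From 95 to 190 cells they were 483 and 417 without 190-cell replicate A and 512 and 446 without replicate B. With spike-ins as the scale the 3 steps called 2911, 1581 and 1908 genes. The 5 other scalings put the higher share between 37.9% and 77.9% for the first step, against 43.4%, between 34.0% and 53.9% for the second, against 48.3%, and between 45.2% and 69.6% for the third, against 46.5%.

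Over the 5 N2 stages, the moderated F test called 14270 of 17778 genes, and 9410 under all 6 scalings. By group means, 7202 of the 14270 (50.5%) were highest at the 4-cell stage, 2661 at 28 cells, 962 at 55, 999 at 95 and 2446 at 190 cells. This ranking followed the scaling. With always-detected probes as the scale, 2398 of 12510 called genes (19.2%) were highest at 4 cells, 3998 at 28 cells and 3854 at 190 cells. With spike-ins 12.4%, and with no scaling 2817 of 12238, were highest at 4 cells. The deposited value table, scaled to its own 75th percentile, put 3994 of 12785 there, and the A probe alone at the main scaling 6315 of 13507. In the 4 comparisons with the 4-cell stage, scaling to always-detected probes moved the median gene by 1.20, 1.13, 1.1 and 1.3 log2 units, in order of stage, relative to the main scaling.

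**Figure D4:**
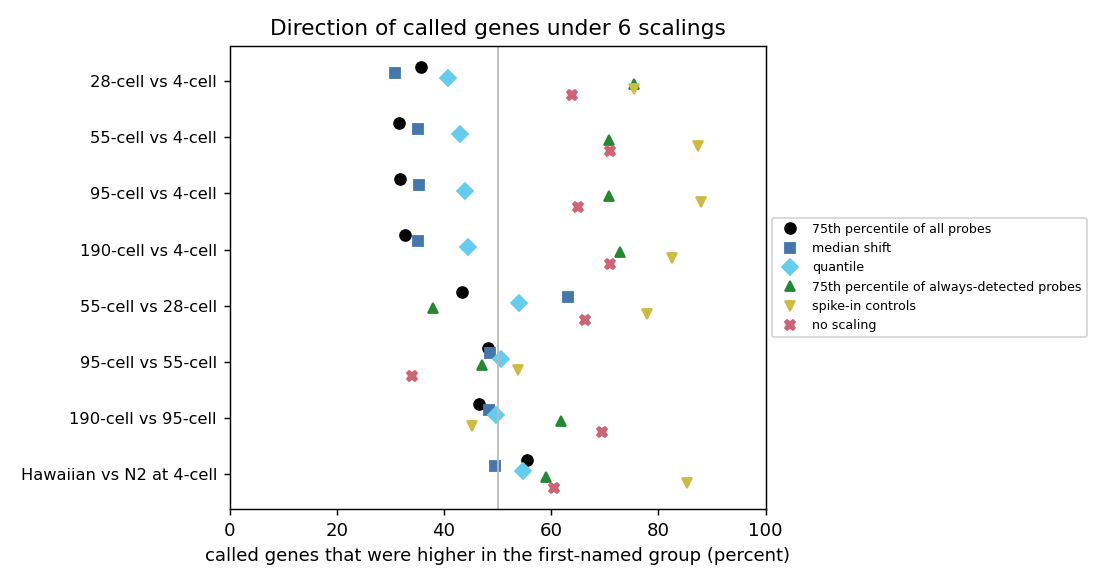
Share of called genes that were higher in the first-named group of each comparison, under 6 ways of scaling the arrays. For the 4 comparisons with the 4-cell stage the share lies below 50% under the first 3 scalings and above it under the others, as with 35.7% and 75.4% at 28 cells.

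Hawaiian and N2 embryos differed at the 4-cell stage. Called genes numbered 2258 of 17779, 1254 higher and 1004 lower in Hawaiian, and 915 and 648 of them by at least 2-fold. Under all 6 scalings 930 were higher and 289 lower, and 799 and 289 of these by at least 2-fold. Spike-ins alone called 289 lower, and median scaling 974 higher. The most extreme scaling in each direction thus largely sets these counts, and their balance depends on the scalings chosen. The share of higher calls was 55.5%, and between 49.5% and 60.5% under the other scalings except spike-ins, which gave 85.3% and moved the median gene by 0.58 log2 units. Detection in Hawaiian only was seen for 232 genes and in N2 only for 69, and under the main scaling the bound reached 4-fold in 44 and 34 of them, while 191 and 58 were called in that direction under all 6 scalings. Without N2 4-cell replicate C, which detected the most genes of its group, 511 genes were detected in Hawaiian only, and without N2 replicate B or Hawaiian replicate B 109 and 107 were detected in N2 only. With the A probe alone the counts were 409 and 129. Of the 232 genes detected in Hawaiian only, 153 were detected at a later N2 stage, as were 64 of the 69 detected in N2 only. Of all 2343 genes detected on no N2 4-cell array, 1700 were detected at a later N2 stage. Of the 12774 detected on every N2 4-cell array, 12119 were detected at all 5 stages. That rule is stricter than detection at a later stage, so it gives no matched base for the 64. At least 2 kept probes were present for 100 of the 232 and 30 of the 69. In 27 and 14 of these, at least 2 probes were detected on all 3 arrays of the strain. The count of calls was 1458 with normexp correction and 1267 when only the 6 arrays of the strains were fitted. It was 2792 of 16050 genes with the A probe alone, and 2714 of 16809 with the deposited value table.

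WBGene00010555 ranked first among the genes detected in both strains and higher in Hawaiian, at 4.44 ± 0.13 (SD, n = 3) against -4.59 ± 0.39 (n = 3) in N2, a log2 difference of 9.03 ± 0.29 (SE, limma adjusted p = 3.04e-10). Of its 2 probes, 1 was detected in both strains, with a difference of 8.71, and the other was detected on no N2 4-cell array, so that the mean is no exact fold. It stayed low in later N2 embryos, at -7.92 ± 0.60 (n = 2) at 190 cells. WBGene00007766 ranked first among the genes detected in both strains and lower in Hawaiian, at -5.02 ± 0.48 (n = 3) in Hawaiian and 3.42 ± 0.16 (n = 3) in N2, a difference of -8.44 ± 0.25 (SE, adjusted p = 1.81e-10). Of its 3 probes, 1 was detected in Hawaiian, with a difference of -5.24, and the others were not well above background there, so that the mean is no exact fold. The gene ranked next was ahead with the A probe only, the brightest probe and the deposited value table, where its values rest on probes not well above background in Hawaiian, while its 1 probe detected there gave -0.95. By means that include such probes it was also ahead with quantile scaling (-8.23 against -8.09), normexp correction (-7.52 against -7.28), and without N2 replicate B (-8.67 against -8.38) or Hawaiian replicate B (-8.38 against -8.31). In N2 the level of WBGene00007766 fell after the 4-cell stage, to -1.97 ± 0.08 (n = 3) at 28 cells.

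Arrays of different groups shared slides, so each comparison was also made with the slide as a block and within slides. The block left 12796 calls for 28 cells, 12121 for 55, 12508 for 95 and 13020 for 190 cells against 4 cells. It left 4458, 2984 and 3301 calls for the 3 later steps, and 2133 for the strains. On each slide that held both groups of a comparison, with 1 array of each, between 99.8% and 100% of the called genes differed in the direction of the group means, to which the same arrays contributed. The strain differences on slide 2 and on slide 4, which share no array, correlated at r = 0.65 across 17768 genes, which are not independent replicates.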

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

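The tests of the strain differences and of the direction of change were chosen only after those results were seen.

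The array carries 91 probes for 13 genes of the related nematode C. briggsae, and these entered no comparison. A set of 26 of them, from 12 genes, was well above background on all 16 arrays, and 44 were on none. Between 34.1% and 46.2% of these probes were above background on an array, against at most 2.61% of the 153 negative control spots. No explanation was tested.

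More genes were called lower than higher after the 4-cell stage. With probes detected on every array as the scale, 75.4% of calls at 28 cells against 4 cells were higher, in place of 35.7%. That scale moves the median gene by 1.20 log2 units. Its probes had to be detected on the 4-cell arrays, which detected the fewest genes on average. It thus leaves out RNA seen only later, and the turn may follow in part from that choice. The majority direction depends on the scaling, which does not tell its cause. The deposited value table, scaled to its own 75th percentile, also turned it (6112 higher and 4134 lower), while the A probe alone at the main scaling left it lower (4455 and 7004). Equal masses of labelled RNA were put on each array, so none of the scalings gives the amount of RNA per embryo. A change in the makeup of the RNA that moves the 75th percentile stays open and was not tested.

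Probes of one gene moved apart between the 4-cell stage and later stages. Of 4876 genes with an A and a B probe above background on all 16 arrays, the ratio of the probes was called for 1509 (30.9%) at 55 cells against 4 cells and 280 (5.74%) at 55 against 28 cells. B probes that the deposited value table leaves out were argued against as the whole cause. Of the 3167 other pairs, 610 (19.3%) were called at 55 against 4 cells and 71 (2.24%) at 55 against 28 cells. That share was 8.59 times as high against the 4-cell stage. Left-out B probes still carried much of the pattern: of their 1709 pairs, fitted separately, 916 (53.6%) and 216 (12.6%) were called. A probe response that compresses every change alike stays open. In pairs matched on the size of the gene's change, ratios at unadjusted p under 0.001 in the moderated test were counted. Their share was 3.57 times as high against the 4-cell stage (95% bootstrap interval 3.09 to 4.15). The size was taken from the median pair, whose own change depends on the scaling, and changes over 2 log2 units were not matched. The matching therefore cannot decide. A change in transcript ends between maternal and embryonic RNA is a candidate explanation, as are cross-hybridisation and the length of the amplified RNA, and none of these was tested.

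Hawaiian and N2 embryos differed in 2258 genes. A shift of the Hawaiian embryos along the change from 4 to 28 cells was argued against as the whole cause. That change accounted for 1.3% of the variance of the strain differences. The covariance with it was 0.243, against 0.0686 in simulated unchanged groups, so a small shift in stage stays open. A shift in stage that follows another course would not be seen. Differences between slides as the whole cause were argued against by the 2133 calls left with slide as a block. A mismatch between a probe and the Hawaiian sequence lowers the Hawaiian signal, so by its direction it would not raise the 930 genes higher in Hawaiian under all 6 scalings, a count known beforehand that does not measure mismatches. For genes lower in Hawaiian mismatches stay open: among genes that differed by at least 2-fold and had at least 2 probes detected on all 3 arrays of the strain with more signal, probes of one gene differed by over 1 log2 unit in 43.9% of 371 lower and 44.8% of 442 higher genes (ratio 0.981, 95% interval 0.84 to 1.14), and in 33.9% and 30.7% among probes of the deposited table. In the form of that test run first, which also required the higher genes' probes to be detected in N2, the counts were 163 of 371 and 61 of 210 (Fisher's exact p = 0.000389). The lower genes' probes did not have to be detected in Hawaiian, so this form treats the sets unequally and cannot decide. The outcome turns on which probes are required, and heritable differences in expression may also contribute, untested.

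In each comparison of 3 arrays with 3, 1 of the 10 splits, the real one, gave as many calls, and 10 splits are too few for a share under 0.05. The real split called 11915 genes at 28 cells against 4 cells, and the highest other split 45. At 95 cells the real split called 12821 and the highest other 0. For the strains the real split called 2258 and the highest other 46. Every other split mixes arrays of both groups, which widens the spread wherever the groups differ. Their low counts therefore do not show how many calls arise without a difference.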

How the results depend on the processing

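The scalings by always-detected probes, by spike-ins and with none, the counts under all 6 scalings and the detection counts were chosen after the data were seen. Of 160 values under other settings, 141 were within 1.5 times the value reported, and of 224 values without one array, 195 were. These totals leave out the numbers of genes higher and lower and the detection counts of the 3 later steps, which also move and were set aside after their values were seen. For the 8 genes at the top of the ranking, every log2 change under the other settings, and 44 of 44 without one array, kept direction and call. Signal over background limits the detection counts, and gene probes gave less signal on the 4-cell arrays. The spike-ins averaged more on the N2 4-cell arrays (log2 14.57) than on later ones. On the Hawaiian 4-cell arrays they averaged 14.07, against 14.28 at 28 cells. Unless stated, the cause was not tested.

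The strain comparison called 1458 genes with normexp correction and 1267 with only the arrays compared, which leaves fewer arrays to estimate the spread. Genes highest at the 4-cell stage numbered 3994 with the deposited value table, 2398 with always-detected probes as the scale, 1464 with spike-ins and 2817 with no scaling. With spike-ins, 2911 genes were called for 55 against 28 cells, 1581 for 95 against 55 and 1908 for 190 against 95. With the A probe only, detection was gained by 1601, 1770, 1633 and 2074 genes at 28, 55, 95 and 190 cells against 4 cells, and by 409 in Hawaiian, and was lost by 96 at 28 cells, 193 at 95, 249 at 190 and 129 in Hawaiian. With the probes of the deposited value table, 109 genes were detected in N2 only. A gene with fewer probes has fewer chances of detection.

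Leaving out one array in turn gave 2811 to 4324 calls for 55 against 28 cells, 1929 to 2651 for 95 against 55 and 2387 to 3358 for 190 against 95. Under all 6 scalings it gave 771 to 1377 genes lower at 55 against 4 cells, 596 to 1535 higher and 301 to 584 lower for 55 against 28, 389 to 659 higher and 317 to 543 lower for 95 against 55, and 483 to 707 higher and 417 to 641 lower for 190 against 95. Detection was lost by 71 to 110 genes at 28 against 4 cells, 143 to 268 at 55, 124 to 239 at 95, 158 to 293 at 190 and 77 to 109 in Hawaiian, and gained by 246 to 511 in Hawaiian. Called counts of the later steps moved by over 1.5 times without 55-cell replicates A or B, 28-cell replicate B or 190-cell replicates A or B. Where 1 array of a group was left, it was assumed to vary like the other groups.

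With the replicate letter as a block, 12077, 12091, 12983 and 12485 genes were called at 28, 55, 95 and 190 cells against 4 cells, and 2273 between strains. Whether letters mark pairs was not settled. Departures from the group mean correlated between 28-cell and 4-cell arrays of one letter at r = 0.35 for A, -0.08 for B and 0.38 for C, and with another letter at most at -0.014, 0.15 and 0.08. The 28-cell and 4-cell arrays of A shared slide 1 and those of C slide 4, while those of B lay on slides 3 and 2. Letter and slide therefore cannot be told apart there. At 95 cells A and C were again above the other letters and B below. The A arrays again shared slide 1, but the C arrays lay on slides 5 and 4. Between strains only A was above, by 0.034 against 0.021. A block for scan day was not run.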

Other observations

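All counts below were chosen only after the data were seen.

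Some transcripts were seen only for part of the time course. Detected on no N2 4-cell array, on all 28-cell arrays and on no array from 55 cells on were 50 genes. Another 75 were off from 4 to 95 cells and on at 190 cells, and 48 were on at 4 and at 190 cells and off at 1 or more stages between. These are counts of detection over groups of 2 and of 3 arrays, with no test of their own.

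Genes called between the strains were also followed in later N2 embryos. Between 28 and 190 cells, 619 of the 930 genes higher in Hawaiian under all 6 scalings (66.6%) and 220 of the 289 lower genes (76.1%) changed in the moderated F test, against 7673 of the 15521 genes not called between strains (49.4%). The difference between these shares was not tested, and the sets differ in other ways: 53.1%, 79.9% and 67.6% of their genes were detected at all 5 N2 stages, with median log2 levels of -3.67, -2.41 and -3.37. Both calls come from one fit, so they share each gene's estimate of the spread, and genes with a low spread are favoured in both. Of the 232 genes detected in Hawaiian and not in N2 at the 4-cell stage, 113 (48.7%) were on in N2 at 28 cells, against 619 of 1426 (43.4%) of those off in both strains.

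The B probes that the deposited value table leaves out followed their genes' A probes less closely. Over the 13 N2 arrays the median r between the A and B probes of a gene was 0.469 for the 1709 pairs with such a B probe and 0.965 for the 3167 other pairs, where both probes were above background on all arrays. The left-out B probes were dimmer, with a median log2 difference from the A probe of -3.71, against 0.37 for the others.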
